A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

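The samples were 9 RNA-seq libraries of *S. cerevisiae* CAT-1, 3 from control fermentations and 3 each from fermentations with the antifoam agents labelled Ind_B and Ind_Z. Per the labels' protocols, total RNA was purified with TRIzol and libraries were made with an Illumina TruSeq kit after enzymatic removal of ribosomal RNA. The submitters' processing notes name TopHat2 2.0.9 and HTSeq 0.6.0 without giving their roles. The authors deposited 1 table of raw read counts per annotated feature, with 6357 rows and 9 columns of whole numbers, and all 9 columns were used. The genome build, the annotation and the strand setting are not given in the sources used here, so genes that overlap on opposite strands are uncertain. Total counts ranged from 5900571 to 18245935 per library.

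Columns were matched to samples by name. The match gave 7 columns a sample, and the columns control12 and control13, which read like no sample title, were assigned to the control group without a replicate number. Row names were matched to the RefSeq gene table of assembly R64, used for names only: 5783 by locus tag and 65 by symbol, 5848 in all, with 509 unmatched rows kept under their own names. Genes were marked as having a near-identical copy where BLAST+ 2.17.0 found another gene at 95% identity or more over at least 50% of the length. Members of such families are uncertain where reads could be shared.

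Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings (6137 genes), library sizes were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 9 libraries, leaving 6 residual degrees of freedom. The quasi-likelihood F-test compared Ind_B with control, Ind_Z with control, Ind_Z with Ind_B and all 3 groups at once. P-values were adjusted by Benjamini-Hochberg and genes were called at an adjusted p under 0.05. Standard errors were taken from the F statistic. CPM were computed from the deposited counts with TMM-scaled library sizes, and log2 CPM used a prior count of 2.

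The design, the alternatives, 38 gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison with control, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 counts and all 3 libraries of one group above all 3 of the other. It took 5 and 5 for Ind_Z against Ind_B, and from each list up to 4 called members or, if none was called, the member of lowest p. For Ind_B fewer qualified and all were named. CLN2 and RNR1 in the account of control13 were picked after their values were seen.

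The lists were general stress, trehalose and glycogen, heat shock, cell wall, oxidative stress, drug resistance, weak organic acids, unfolded proteins, osmotic stress, ergosterol, phospholipids, fatty acids, sphingolipids, beta-oxidation, glycolysis, hexose transport, the respiratory chain, mitochondrially encoded genes and the tricarboxylic acid cycle. The others were ribosomal proteins, ribosome biogenesis, amino acids, sulfur, nitrogen catabolite repression, iron, phosphate, zinc and copper, thiamine, hypoxic genes, seripauperins, flocculation, the proteasome, autophagy, S phase, histones, meiosis, quiescence and mating. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, without comparing them to other genes. Counts of called members are given over all genes tested and adjusted over the list alone.

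The alternatives were DESeq2 1.42.0 (a likelihood ratio test for all 3 groups), RLE and upper-quartile factors, no filter on low counts, a mean count of at least 50, leaving out 36 rows (mitochondrially encoded genes and the 20 most abundant genes), a fit on the 6 libraries of a comparison, a test against a 1.5-fold change, and leaving out each library in turn. Limma-voom with sample quality weights and a replicate block on the 6 antifoam libraries were added after seeing the data. Values without control13 belong to the planned leave-one-out fits. Only that fit is given gene by gene and list by list, because control13 stood apart once the data were seen. For the similarity of the antifoam responses, 20 data sets without group effects were simulated. All 9 libraries, controls included, were redrawn from each gene's overall mean, with the same dispersion of a gene in every library. The redrawn controls served both comparisons.

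The scripts were tested on simulated data drawn from the real means, dispersions and library sizes, with 200 genes changed in Ind_Z. For Ind_Z against control, over 6123 genes, 20%, 68%, 100% and 98% of the genes changed by 1.5, 2, 4 and 8-fold were called, with 10 calls among unchanged genes. For Ind_Z against Ind_B the shares were 26%, 72%, 100% and 100%, with 6 such calls. A list moved by 1.5-fold was called by camera (adjusted p = 2.88e-24, and 0.00118 with an estimated correlation) and 0 of the other lists were called by either. The simulated genes were drawn independently, with the same dispersion of a gene in every library. The list test therefore does not cover lists whose members vary together. In the data the estimated correlation was 0.634 for ergosterol genes (Ind_B against control) and 0.843 for ribosomal protein genes (Ind_Z against Ind_B).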

Results

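RNA was sequenced from CAT-1, a *Saccharomyces cerevisiae* strain used by Brazilian fuel-ethanol plants, grown in fed-batch fermentations of sugar cane molasses. The cells went through 5 fermentation cycles separated by acid washes and were sampled at hour 4 of the last cycle. The 9 libraries formed 3 groups of 3: untreated control cultures and cultures given an antifoam agent labelled Ind_B or Ind_Z. Read counts were available for 6357 rows of genes and other features. Total counts were 18245935, 12296693 and 6585639 in the control libraries control1, control12 and control13. They were 13437215, 9492360 and 17943055 in Ind_B replicates 1, 2 and 3, and 15091487, 5900571 and 10027292 in Ind_Z replicates 1, 2 and 3. Levels are CPM scaled by TMM factors, given as mean ± SD with n = 3 libraries per group, and fold changes are on the log2 scale ± SE. Gene positions in the authors' build were not given in the sources used here.

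The Ind_Z libraries resembled each other closely, the Ind_B libraries were about as close to control12 as to each other, and 1 control library stood apart. Spearman correlations over genes were 0.976 to 0.988 within Ind_B and 0.993 to 0.995 within Ind_Z. Among controls, control1 and control12 correlated at 0.995, but control13 reached only 0.956 and 0.954 with them. In control13 the G1 cyclin gene CLN2 was at 518 CPM against 48.1 and 33 in the other controls, and the ribonucleotide reductase gene RNR1 was at 2930 CPM against 275 and 312. Cytosolic ribosomal protein genes were higher in control13 than in the mean of the other 2 controls by a median of 0.99, glycolysis genes by 1.04 and ergosterol genes by 0.59. Counts of calls without control13 are given for each comparison. With control12, Ind_B replicates 1, 2 and 3 correlated at 0.988, 0.98 and 0.993, against 0.983 and 0.988, 0.983 and 0.976, and 0.988 and 0.976 with the other libraries of their own group.

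**Figure D1:**
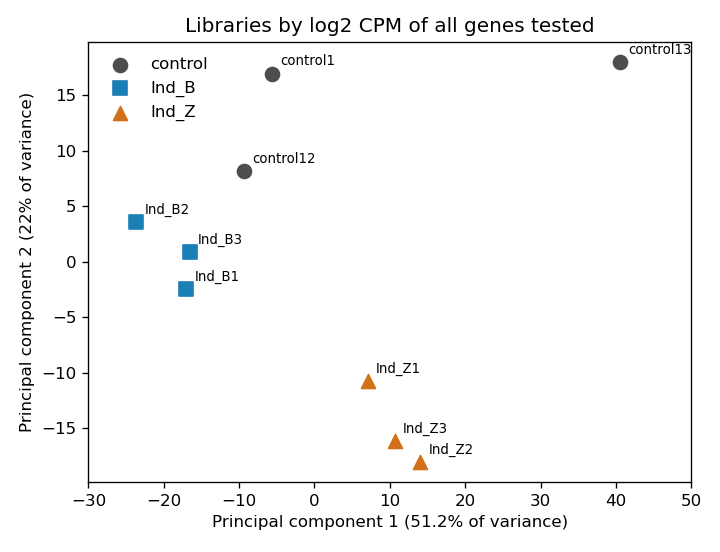
Principal components of the log2 CPM of all genes tested, with component 1 (51.2% of the variance) on the horizontal axis, component 2 (22%) on the vertical axis and 1 point per library. The control library control13 lies at 40.57 on component 1, and the Ind_Z libraries lie at 7.07 to 13.99, apart from the Ind_B libraries at −23.69 to −16.58.

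The comparison of Ind_B with control asked which transcripts differed in cells fermenting with that antifoam. Among the genes that fell were ERG5, CYB5 and FAA4, which act in sterol and lipid metabolism. ERG5, encoding the C-22 sterol desaturase of the ergosterol pathway, was at 325 ± 88.5 CPM in Ind_B against 1183 ± 439 in control, a change of −1.86 ± 0.29. CYB5, encoding cytochrome b5, fell by 1.59 ± 0.21, from 157 ± 51 to 52.3 ± 3.33 CPM. FAA4, a long-chain fatty acyl-CoA synthetase gene, fell by 1.53 ± 0.23, from 1340 ± 285 to 464 ± 101 CPM. The genes that rose were JLP1, a sulfonate dioxygenase gene, at 44.3 ± 3.23 CPM against 13.9 ± 4.66 (change 1.66 ± 0.21), and MMP1, encoding the S-methylmethionine permease, at 187 ± 13.4 CPM against 97.2 ± 10.1 (0.94 ± 0.14).

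The other genes that fell were PIR3, SCM4, PBI1 and AHP1. PIR3, a cell wall glycoprotein gene, changed by −2.83 ± 0.42, from 436 ± 237 to 61.2 ± 27.2 CPM. AHP1, a thioredoxin peroxidase gene, fell by 1.13 ± 0.17, SCM4 fell by 1.35 ± 0.2 and PBI1 fell by 1.24 ± 0.17. In total 9 of 6137 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 higher and 7 lower in Ind_B, at adjusted p of 0.043 to 0.0467. Several genes with large differences stayed just short of the threshold at an adjusted p of 0.0558 in edgeR's quasi-likelihood test. OLE1, the fatty acid desaturase gene, was at 1004 ± 165 CPM against 3945 ± 1927 (−1.97 ± 0.34), HXT2, a hexose transporter gene, at 147 ± 39.4 against 22.1 ± 5.05 (2.73 ± 0.46), CTT1, the cytosolic catalase gene, at 102 ± 13.6 against 268 ± 77.2 (−1.39 ± 0.23), and IZH1 at 58.8 ± 0.801 against 114 ± 24.7 (−0.95 ± 0.16). Without control13 OLE1 (adjusted p = 0.0297), CTT1 (0.042) and IZH1 (0.034) were called and HXT2 (0.059) was not.

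Among the gene lists fixed beforehand, camera with a preset correlation called 19 of 38 for Ind_B against control, 6 higher and 13 lower. Ergosterol biosynthesis had a median change of −0.89 with 24 of 26 members lower; 1 member fell over all genes tested, and adjusted over the list alone 21 fell and 2 rose (adjusted p = 0.409 with an estimated correlation). Without control13 its median was −0.66 and 7 members fell. Fatty acid synthesis had a median of −0.4 (−0.18 without control13), with FAA4 the member that fell and 6 falling when adjusted over the list alone. Nuclear genes of the respiratory chain had a median of −0.49; 0 members passed edgeR's test over all genes and 18 fell adjusted over the list alone, with QCR2 at −0.68 ± 0.16. The cell wall list had a median of −0.44 (−0.26 without control13), with PIR3 the member that fell over all genes and 8 falling against 1 rising adjusted over the list alone. Without control13, 5 fatty acid and 4 cell wall genes fell over all genes. Each of these 3 lists also had an adjusted p = 0.409 with an estimated correlation, and without control13 the lowest such p of the 38 lists was 0.145.

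Cytosolic ribosomal protein genes had a median of −0.61 in Ind_B against control, with 133 of 135 members lower; 0 passed edgeR's test over all genes or adjusted over the list alone, and the median without control13 was −0.2. Amino acid biosynthesis genes had a median of −0.63 (−0.24 without control13; LEU1 −1.01 ± 0.27, and −0.59 without control13), the tricarboxylic acid cycle −0.38 (−0.21 without control13; SDH2 −0.52 ± 0.15, and −0.33 without control13) and S phase genes −0.48 (−0.14 without control13; PCL1 −3.9 ± 0.95, adjusted p = 0.114). PCL1 was at 441 CPM in control13 against 35.9 and 25.9 in the other controls, and without control13 its change was −1.49 and called (adjusted p = 0.0297). With all libraries no member of these 3 lists passed edgeR's test over all genes or adjusted over the list alone, and without control13 2 S phase genes fell over all genes. Trehalose and glycogen genes had a median of −0.53 (−0.24 without control13; GSY2 −1.18 ± 0.25), with 6 members falling adjusted over the list alone; without control13 3 fell over all genes, GSY2 among them (−0.8, adjusted p = 0.0297). The nitrogen catabolite repression list had a median of −0.19 (MEP3 −0.56 ± 0.13), with 3 falling and 1 rising adjusted over the list alone. Each of these 6 lists, ribosomal proteins included, had an adjusted p = 0.455 with an estimated correlation. Glycolysis genes had a median of −0.38 (−0.04 without control13; adjusted p = 0.627 with an estimated correlation; HXK1 −1.19 ± 0.34, and −0.64 without control13). Histone genes had a median of −0.54 (0.04 without control13; adjusted p = 0.558 with an estimated correlation; HHT2 −0.91 ± 0.34, and −0.29 without control13). In these 2 lists no member passed edgeR's test over all genes or adjusted over the list alone. The oxidative stress list had a median of −0.16 (−0.04 without control13; adjusted p = 0.521 with an estimated correlation), with AHP1 the member that fell over all genes and 4 falling adjusted over the list alone. Without control13 camera's calls ended for glycolysis (adjusted p = 0.876), histones (0.839) and oxidative stress (0.0938).

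Of the lists called higher in Ind_B, sulfur assimilation and methionine genes had a median of 0.3 with 2 members rising, JLP1 and MMP1, and adjusted over the list alone 10 rose and 1 fell (adjusted p = 0.455 with an estimated correlation). Meiosis and sporulation genes had a median of 0.42 with 10 rising adjusted over the list alone (HOP1 0.86 ± 0.15), the iron regulon 0.27 with 9 (SIT1 0.88 ± 0.18) and mating and haploid-specific genes 0.35 (0.21 without control13) with 6 (FUS3 0.84 ± 0.14). These 3 lists had an adjusted p = 0.409 with an estimated correlation, and in control13 they lay below the other controls by medians of −0.57, −0.33 and −0.47. Without control13 1 meiosis gene, HOP1, and 2 mating genes, FUS3 among them, rose over all genes (adjusted p = 0.0453 for both named), and 3 sulfur genes. Heat shock genes had a median of 0.32 with 4 rising adjusted over the list alone (CUR1 0.96 ± 0.23), at an adjusted p = 0.475 with an estimated correlation. Their median log2 CPM relative to the mean of each gene was −0.581, 0.001 and −0.447 in control1, control12 and control13. In Ind_B replicates 1, 2 and 3 it was 0.007, 0.124 and −0.034, so control12 lay among the Ind_B libraries. Hexose transport genes had a median of 0.27, with 3 rising and 2 falling adjusted over the list alone (adjusted p = 0.502 with an estimated correlation).

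The remaining 19 lists were not called for Ind_B against control. Their medians, with those without control13 in parentheses, were −0.13 (−0.13) for general stress, 0.13 (0.06) for pleiotropic drug resistance, 0.16 (0.17) for weak organic acids, −0.09 (0.03) for the unfolded protein response, 0.16 (0.19) for osmotic stress, 0.02 (0.07) for phospholipid synthesis, −0.1 (−0.0032) for sphingolipid synthesis and −0.01 (−0.05) for beta-oxidation. They were −0.13 (−0.18) for mitochondrially encoded genes, −0.03 (−0.09) for ribosome biogenesis, 0.01 (0.08) for phosphate starvation, −0.03 (0.04) for zinc and copper, 0.02 (0.02) for thiamine, −0.34 (0.02) for hypoxic genes and 0.3 (0.36) for the seripauperin family, whose reads may be shared among near-identical copies. They were 0.16 (0.2) for flocculation, −0.07 (−0.1) for the proteasome, 0.13 (0.07) for autophagy and −0.03 (0.05) for quiescence, where the test's direction was upward. Without control13 the test's direction turned upward for unfolded proteins, sphingolipids and zinc and copper and stayed downward for hypoxic genes. Without control13 camera called 5 of these lists, osmotic stress, seripauperins and flocculation higher and ribosome biogenesis and the proteasome lower. With an estimated correlation these 5 calls were lost, at adjusted p of 0.468, 0.349, 0.411, 0.566 and 0.503 in that order.

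The count of calls for Ind_B against control depended on single libraries: edgeR called 332 genes without control12 and 45 without control13, including all 9. It called 0 without control1 (1233 at an unadjusted p under 0.05), 0 without any 1 of the 3 Ind_B libraries (816 to 1067) and 0 without Ind_Z replicate 1 or 3 (961 and 964). Without Ind_Z replicate 2 it called 1, which was none of the 9, while DESeq2 on all libraries called 301.

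The comparison of Ind_Z with control addressed the same question for the other antifoam. Among called genes with a mean of at least 50 counts, hexose transporter and stress protein genes rose most. HXT2 was at 259 ± 185 CPM in Ind_Z against 22.1 ± 5.05 in control (change 3.54 ± 0.47), and HXT1, a low-affinity transporter gene, was at 296 ± 143 against 26.1 ± 5.78 (3.49 ± 0.41). HSP30, a plasma membrane stress protein gene, rose from 886 ± 181 to 4207 ± 1063 CPM (2.25 ± 0.29). BTN2, which acts in the sorting of misfolded proteins, rose from 153 ± 66.3 to 646 ± 84.9 CPM (2.07 ± 0.28). Genes that fell included HES1, an oxysterol-binding protein gene, from 30.8 ± 3.62 to 9.83 ± 1.3 CPM (−1.63 ± 0.18), and GAP1, the general amino acid permease gene, from 222 ± 34.1 to 100 ± 39.9 CPM (−1.16 ± 0.24).

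The next largest rises under that limit were those of DDR2 (2.05 ± 0.37), a stress gene, TMA10 (2.02 ± 0.42), OPI10 (1.95 ± 0.34), YDL023C (1.93 ± 0.2), NIS1 (1.82 ± 0.28) and SPG1 (1.73 ± 0.32). YDL023C was not in the reference gene table, so its overlap with other genes was not checked. The other largest falls were those of YHB1, the flavohemoglobin gene (−1.51 ± 0.25), ERG5 (−1.34 ± 0.28), PBI1 (−1.33 ± 0.17), CYB5 (−1.13 ± 0.21), MVD1 of the mevalonate pathway (−1.12 ± 0.22), SCM4 (−1.12 ± 0.2), HSP33 (−1.07 ± 0.21) and LRS4 (−0.95 ± 0.2). HSP33 has a near-identical copy, which makes its count uncertain. In total 131 of 6137 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 106 higher and 25 lower in Ind_Z, with adjusted p of 0.00588 for HXT1 and HES1.

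**Figure D2:**
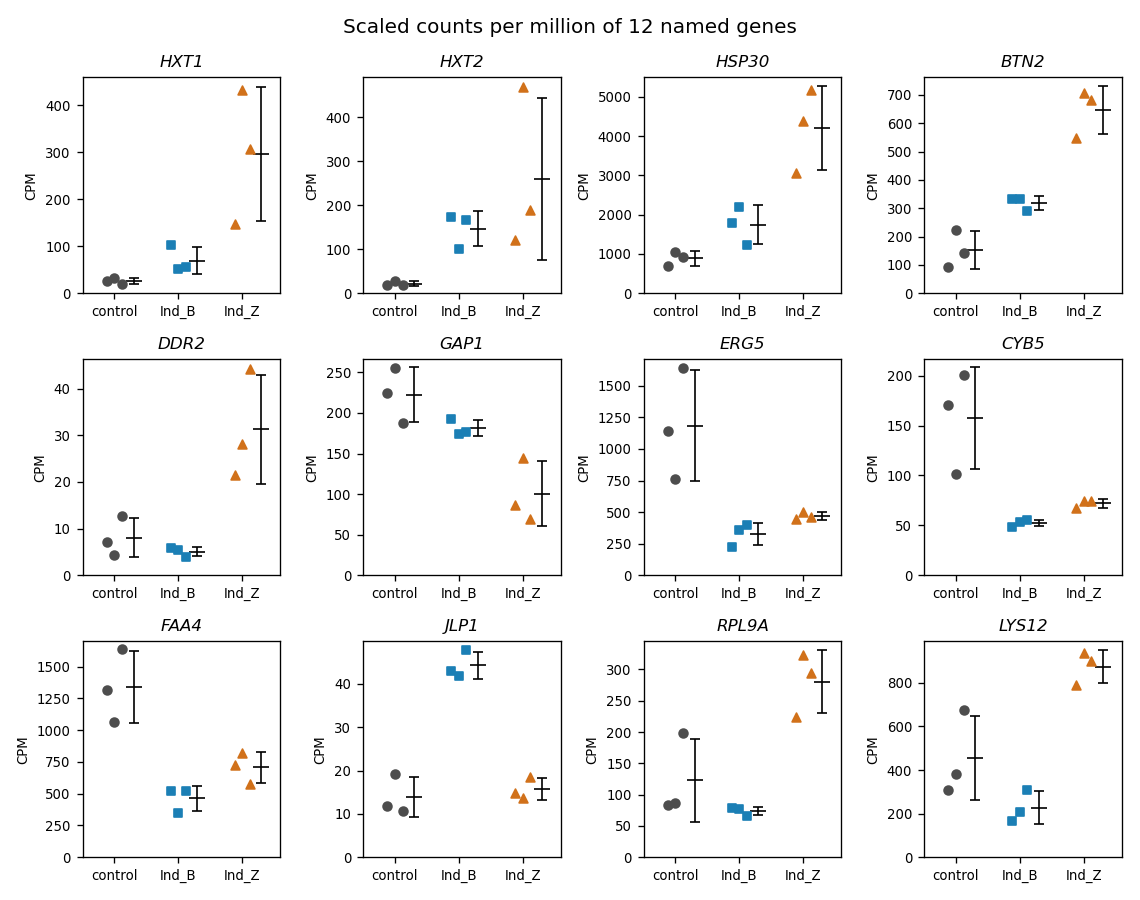
TMM-scaled CPM on the vertical axis for named genes in the 3 groups, with 1 point per library and bars for the mean ± SD of 3 libraries. HXT1 was at 20.5 to 32 CPM in the controls and at 147 to 432 in Ind_Z, while ERG5 was at 764 to 1640 in the controls and at 225 to 501 in the 6 antifoam libraries.

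Camera called 13 of 38 lists for Ind_Z against control, 9 higher and 4 lower. Heat shock and protein folding genes had a median of 0.71, with all 24 members higher; 7 rose over all genes tested and 18 adjusted over the list alone (adjusted p = 0.3 with an estimated correlation, and 0.0281 by fry). Besides BTN2, these included the Hsp70 gene SSA4 (1.48 ± 0.25), its nucleotide exchange factor gene FES1 (1.53 ± 0.25) and CUR1 (1.44 ± 0.23). In the general stress list 6 of 30 members rose, and adjusted over the list alone 8 rose and 3 fell (median 0.23, and 0.39 without control13; adjusted p = 0.687 with an estimated correlation). Its risers included DDR2, SSA4, the cell wall protein gene SPI1 (1.48 ± 0.25) and HSP12 (2.69 ± 0.4), which was at 0.969 ± 0.386 CPM in control and 5.81 ± 2.44 in Ind_Z. In the weak organic acid list 3 of 18 members rose, HSP30, SPI1 and the polyamine exporter gene TPO2 (1.09 ± 0.19, a near-identical copy exists), and 6 rose adjusted over the list alone (median 0.33; adjusted p = 0.3 with an estimated correlation, and 0.0281 by fry). Without control13, 14 heat shock, 12 general stress and 7 weak acid genes rose over all genes and 2 general stress genes fell.

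Hexose transport genes were called higher although their median was −0.03, with 10 members higher and 11 lower; 5 of 21 rose over all genes and 5 adjusted over the list alone (adjusted p = 0.687 with an estimated correlation). They included HXT2, HXT1, HXT5 (0.79 ± 0.16) and the glucose-sensing regulator gene MTH1 (0.85 ± 0.17). Without control13 camera's call of this list ended (adjusted p = 0.26), while its median was −0.00031, 6 members rose and 1 fell. Sulfur assimilation genes had a median of 0.42, with MET3, the ATP sulfurylase gene, the 1 member that rose (1.12 ± 0.19) and 8 rising adjusted over the list alone (adjusted p = 0.687 with an estimated correlation). Osmotic stress genes had a median of 0.26 (0.51 without control13) with 7 rising adjusted over the list alone, at an adjusted p = 0.547 with an estimated correlation. Among them ENA1 (0.69 ± 0.19) had the lowest p and has a near-identical copy, which makes its count uncertain. The unfolded protein response had a median of 0.14 (0.5 without control13) with 5 rising (ERO1 0.64 ± 0.15), at an adjusted p = 0.782 with an estimated correlation. Ribosomal protein genes had a median of 0.37 and 1 riser, RPL28 (0.88 ± 0.14), both over all genes and adjusted over the list alone; without control13 the median was 0.81 and 123 rose. Amino acid biosynthesis genes had a median of 0.31 with 0 passing edgeR's test over all genes or adjusted over the list alone (LEU9 0.63 ± 0.15); without control13 the median was 0.62 and 28 rose. These last 2 lists had an adjusted p = 0.827 with an estimated correlation (0.407 and 0.501 without control13). Without control13, 11 sulfur, 8 osmotic stress and 9 unfolded protein genes rose over all genes, and ENA1, ERO1 and LEU9 were called (adjusted p of 0.0221, 0.0113 and 0.00208).

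Of the lists called lower, nitrogen catabolite repression had a median of −0.38, with 5 of 30 members falling over all genes and 10 adjusted over the list alone (adjusted p = 0.3 with an estimated correlation, and 0.0281 by fry). They included GAP1, the ammonium permease genes MEP2 (−0.92 ± 0.18) and MEP3 (−0.73 ± 0.13), and DAL7 (−0.9 ± 0.14), and without control13 11 fell and 1 rose over all genes. Ergosterol genes had a median of −0.55 (−0.42 without control13). ERG5 and MVD1 fell while the sterol regulator genes UPC2 (0.92 ± 0.14) and ECM22 (0.86 ± 0.13) rose. Adjusted over the list alone 15 fell and 2 rose (adjusted p = 0.782 with an estimated correlation), and 4 fell and 2 rose over all genes without control13. Respiratory chain genes had a median of −0.45 (−0.23 without control13; RIP1 −0.52 ± 0.14; adjusted p = 0.687 with an estimated correlation). Beta-oxidation genes had a median of −0.27 (FOX2 −0.51 ± 0.14; adjusted p = 0.3 with an estimated correlation, and 0.0281 by fry), and without control13 camera's call ended (adjusted p = 0.0564). In the respiratory and beta-oxidation lists 0 members passed edgeR's test over all genes or adjusted over the list alone, and without control13 2 and 3 fell, with RIP1 and FOX2 called (adjusted p of 0.0408 and 0.0293).

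Members of lists that were not called also changed in Ind_Z. In the hypoxic list 3 members rose, NCE102 (1.69 ± 0.22), the ADP/ATP carrier gene AAC3 (1.25 ± 0.27) and UPC2 (median −0.02, test upward); without control13 the median was 0.4, 5 members rose, 1 fell and camera called the list higher (adjusted p = 0.00829, but 0.574 with an estimated correlation). In the drug resistance list RSB1 (1.1 ± 0.16) and RPN4, the proteasome gene regulator (0.74 ± 0.13), rose (median −0.0046, test upward; 0.009 without control13, with 5 rising and 1 falling), and RPN4 was the 1 riser of the proteasome list (median −0.02; −0.04 without control13, with 1 rising and 1 falling). In the phosphate list PHO3 rose (1.06 ± 0.2) and GIT1 fell (−0.83 ± 0.12; median 0.1, and 0.27 without control13, with 7 rising and 1 falling), and PHO3 was the 1 riser of the thiamine list (median 0.0024, and 0.0073 without control13, with 2 rising, 2 falling and the test downward). SPG1 and MPC3 (1.45 ± 0.28) rose and HSP33 fell in the quiescence list (median 0.03, and 0.01 without control13, with 2 rising and 2 falling), and PRM1 (1.27 ± 0.25) and FUS3 (0.68 ± 0.15) rose in the mating list (median −0.26, test upward). Without control13 the mating median was −0.07, the test's direction was downward, and 4 members rose and 4 fell. Single risers were SPI1 in the cell wall list (median −0.02, test upward; without control13 0.3, with 8 rising and called higher by camera, but at an adjusted p = 0.599 with an estimated correlation), INM1 (0.61 ± 0.13) in phospholipid synthesis (median 0.07), FIT1 (1.01 ± 0.22) in the iron regulon (median 0.1) and NRG1 (0.93 ± 0.2) in flocculation (median 0.16). Without control13 the medians of the last 3 were 0.13, with 6 rising, 0.03, with 4 rising, 3 falling and the test downward, and 0.2, with 3 rising and 1 falling. DAL7 was the 1 member that fell in the tricarboxylic acid and glyoxylate list (median −0.16; 0.03 without control13, with 1 rising, 2 falling and the test downward).

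The other lists had no call and no member that passed for Ind_Z against control. Their medians, with those without control13 in parentheses, were −0.19 (0.09) for trehalose and glycogen, −0.18 (−0.06) for oxidative stress, −0.05 (0.18) for fatty acid synthesis, 0.17 (0.26) for sphingolipid synthesis, 0.03 (0.5) for glycolysis, −0.14 (−0.25) for mitochondrially encoded genes and 0.07 (−0.0095) for ribosome biogenesis. They were 0.08 (0.14) for zinc and copper (test downward in both), −0.1 (0.03) for the seripauperin family (test upward), −0.1 (−0.21) for autophagy, −0.15 (0.12) for S phase genes, 0.26 (0.83) for histones and 0.02 (−0.11) for meiosis. Without control13 camera called sphingolipid synthesis, glycolysis, S phase genes and histones higher, with 8, 11, 16 and 7 members rising and 2 S phase genes falling. With an estimated correlation these 4 calls were lost (adjusted p of 0.501, 0.407, 0.574 and 0.501). Of the other lists without control13, fatty acid synthesis had 4 members rising and 3 falling, autophagy 2 and 5, zinc and copper 2 and 3, ribosome biogenesis 1 and 3, oxidative stress and meiosis 1 and 1 each and seripauperins 1 rising. The test's direction for trehalose and glycogen stayed downward.

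The number of calls for Ind_Z against control was 1213 without control13, 809 higher and 404 lower, including all 131, so the share higher moved from 80.9% to 66.7%. It was 22 without control1, 64 without Ind_B replicate 1, and 60, 21 and 16 without Ind_Z replicates 1, 2 and 3, while DESeq2 called 446.

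The comparison of Ind_Z with Ind_B asked whether the antifoams left different transcript profiles. DDR2, LYS12 and RPL9A were among the genes higher in Ind_Z. DDR2 was at 31.3 ± 11.7 CPM in Ind_Z against 5.06 ± 0.983 in Ind_B (2.64 ± 0.38), LYS12, the homoisocitrate dehydrogenase gene, at 875 ± 76.3 against 228 ± 74 (1.94 ± 0.31), and RPL9A at 281 ± 50.9 against 74.1 ± 6.88 (1.92 ± 0.31). JLP1 was lower, at 15.7 ± 2.53 CPM against 44.3 ± 3.23 (−1.49 ± 0.21), and so were HES1 (−1 ± 0.18), DAL7 (−0.76 ± 0.14) and CUE2 (−0.64 ± 0.1). The next largest rises among called genes with a mean of at least 50 counts were those of YFR052C-A (1.83 ± 0.27) and YER053C-A (1.82 ± 0.29). YFR052C-A is a row absent from the reference gene table. Its overlap with other genes was therefore not checked, and its count may hold reads of another gene. In total 26 of 6137 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 22 higher and 4 lower in Ind_Z, with adjusted p from 0.0361 to 0.0499 among the genes named.

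Camera called 21 of 38 lists for Ind_Z against Ind_B, 16 higher and 5 lower. Ribosomal protein genes had a median of 0.99 with 134 of 135 members higher. Over all genes RPL9A, RPS8B (1.16 ± 0.2) and RPL28 (0.99 ± 0.14) rose, adjusted over the list alone 124 rose, and without control13 129 rose over all genes. Amino acid biosynthesis genes had a median of 0.83, with LYS12 the 1 riser over all genes, 34 rising adjusted over the list alone and 41 over all genes without control13. In the general stress list DDR2 and HSP12 (2.13 ± 0.36) rose, and adjusted over the list alone 12 rose and 3 fell (median 0.5). The cell wall list had a median of 0.51 with 6 rising adjusted over the list alone (PIR3 2.22 ± 0.41), the unfolded protein response 0.45 with 4 (KAR2 1 ± 0.23), fatty acid synthesis 0.52 with 1 (ELO2 0.97 ± 0.22) and weak organic acids 0.17 with 6 rising and 1 falling (HSP30 1.28 ± 0.28); the weak acid call of camera ended without control13 (adjusted p = 0.0686). Histone genes had a median of 0.82, with 8 rising and 1 falling adjusted over the list alone (HTA2 1.28 ± 0.34). Each of these lists had an adjusted p = 0.477 with an estimated correlation, and without control13 the lowest such p of the 38 lists was 0.229. Without control13, 15 general stress genes rose over all genes and 1 fell, 14 cell wall, 12 unfolded protein, 10 fatty acid and 8 histone genes rose, and 6 weak acid genes rose and 1 fell. PIR3, KAR2, ELO2, HSP30 and HTA2, uncalled over all genes with all libraries, were called without it.

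Heat shock genes had a median of 0.44 with 3 rising adjusted over the list alone (BTN2 1.02 ± 0.27), and osmotic stress genes 0.37 with 2 (GPD1 1.38 ± 0.38); both had an adjusted p = 0.488 with an estimated correlation. Glycolysis had a median of 0.52 with 6 rising and 1 falling adjusted over the list alone (HXK1 1.82 ± 0.35), trehalose and glycogen 0.25 with 6 rising and 3 falling (GDB1 0.77 ± 0.19) and sphingolipid synthesis 0.32 with 1 rising (SUR1 0.87 ± 0.21). The hypoxic list had a median of 0.28 with NCE102 rising over all genes (1.28 ± 0.22) and 2 adjusted over the list alone. These 4 lists had an adjusted p = 0.518 with an estimated correlation. Ergosterol genes had a median of 0.38 (ERG25 0.72 ± 0.24; adjusted p = 0.524 with an estimated correlation), with 0 passing edgeR's test over all genes or adjusted over the list alone, and 7 rising without control13. S phase genes had a median of 0.28 with 6 rising and 1 falling adjusted over the list alone (CDC21 1.73 ± 0.41; adjusted p = 0.574 with an estimated correlation). Without control13, 5 heat shock, 6 osmotic stress and 8 hypoxic genes rose over all genes, and the counts rising and falling were 17 and 1 for glycolysis, 8 and 3 for trehalose and glycogen, 8 and 1 for sphingolipids and 18 and 3 for S phase genes. BTN2, GPD1, HXK1, GDB1, SUR1, ERG25 and CDC21 were called over all genes without control13 and not with it.

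The lists called lower in Ind_Z than in Ind_B were meiosis (median −0.39, 1 falling adjusted over the list alone; REC102 −0.98 ± 0.22), mating genes (−0.32, 7 falling and 1 rising; SAG1 −0.55 ± 0.14), beta-oxidation (−0.18, 2 falling; FOX2 −0.72 ± 0.14; not called by camera without control13, adjusted p = 0.0686) and nitrogen catabolite repression (−0.16, DAL7 falling over all genes, 8 falling and 1 rising adjusted over the list alone). These 4 had an adjusted p = 0.477 with an estimated correlation. The iron regulon had a median of −0.27 with 2 falling adjusted over the list alone (FRE1 −0.52 ± 0.13; adjusted p = 0.486 with an estimated correlation). Without control13, 11 meiosis, 7 mating, 5 beta-oxidation, 9 nitrogen and 7 iron genes fell over all genes, and 1 of each of the last 4 rose. REC102, SAG1, FOX2 and FRE1 were called without control13 and not with it. JLP1 was the 1 member that fell in the sulfur list, which was not called (median 0.11), and DAL7 the 1 that fell in the tricarboxylic acid list (0.23). The other medians without a call were 0.08 for oxidative stress, −0.06 for drug resistance (test upward), 0.07 for phospholipids, 0.03 for hexose transport, 0.13 for the respiratory chain, −0.03 for mitochondrially encoded genes (test upward) and 0.08 for ribosome biogenesis. They were 0.09 for phosphate, −0.002 for zinc and copper (test upward), −0.14 for thiamine, −0.35 for seripauperins, 0.02 for flocculation (test downward), 0.03 for the proteasome, −0.2 for autophagy and −0.04 for quiescence (test upward). Without control13 the test's direction turned downward for drug resistance and for zinc and copper, and 11 autophagy and 2 tricarboxylic acid genes fell while 2 and 9 rose.

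**Figure D3:**
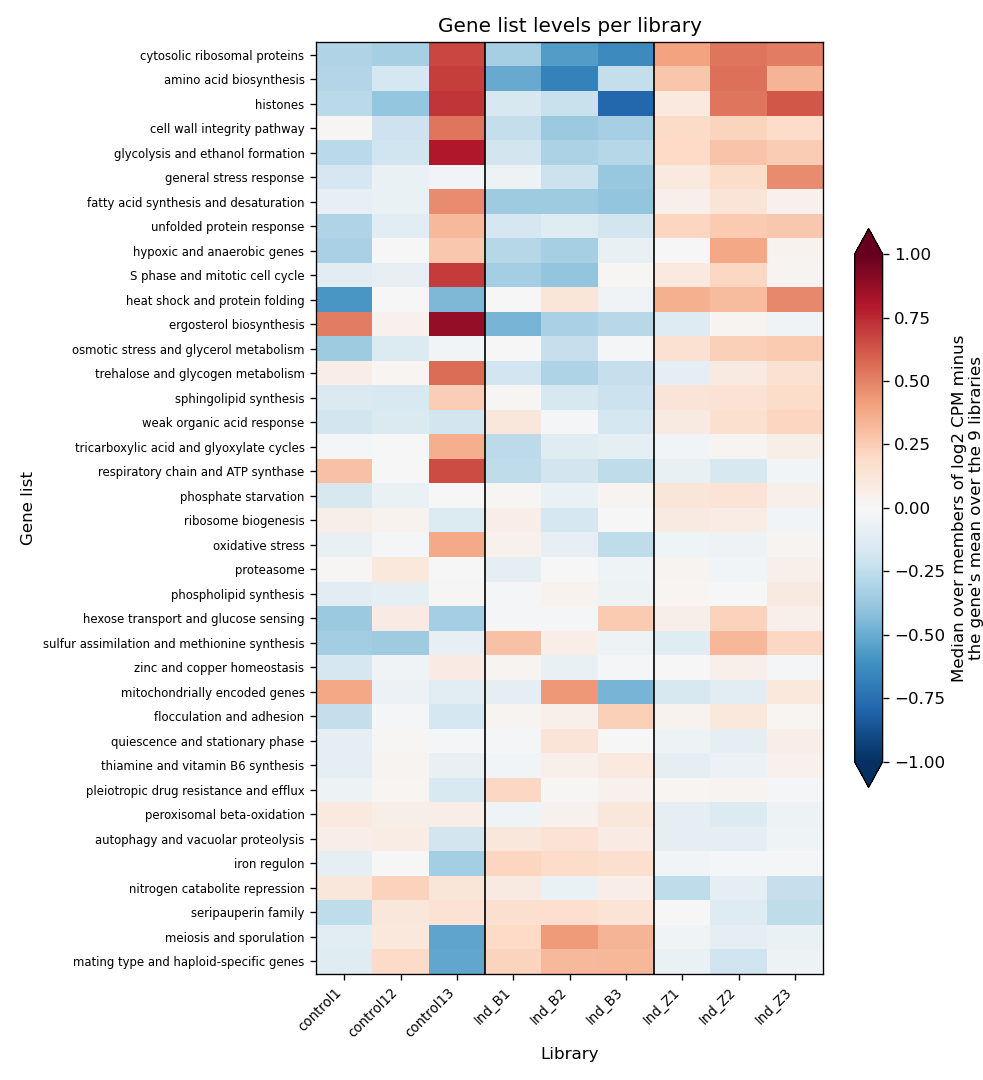
Gene lists in rows and libraries in columns, coloured by the median over members of the log2 CPM minus the gene's mean over the 9 libraries. The ribosomal protein list lies at 0.4 to 0.54 in Ind_Z, at −0.64 to −0.33 in Ind_B and at 0.67 in control13.

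The calls for Ind_Z against Ind_B rose to 1453 without control13 (878 higher, 60.4% against 84.6%), including all 26. The controls enter that fit through the shared estimate of the spread, the filter and the scaling. They were 78 without control1, 48 without control12, 13 without Ind_Z replicate 1, and 0 without any 1 of the other 5 antifoam libraries (917 to 1417 at an unadjusted p under 0.05 in edgeR), while DESeq2 called 631.

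A test for any difference among the 3 groups called 123 of 6137 genes by edgeR's quasi-likelihood test, and 1467 without control13, including all 123. The count was 390 without control12, 12 without control1, 24, 52 and 77 without Ind_B replicates 1, 2 and 3, 35 without Ind_Z replicate 1 and 0 without Ind_Z replicate 2 or 3 (1040 and 1035 at an unadjusted p under 0.05), while DESeq2 called 911.

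The last comparison set the responses to the antifoams beside each other. ERG5, CYB5, SCM4 and PBI1 were called lower in both, where independent lists of 7 and 25 genes would share 0.0285, and 0 genes were called higher in both by edgeR against 0.0345 (1170 and 1183 genes had an unadjusted p under 0.05 in the separate comparisons). Without control13, 12 lower genes (2.35 for independent lists) and 4 higher genes (1.18) were shared. Across genes, which are not independent replicates, the fold changes against control correlated at r = 0.44 and rho = 0.314. Groups without any effect, simulated against the same controls, gave r = 0.498 on average (0.475 to 0.53) and rho = 0.474. The covariance was 0.0739 against 0.028 simulated, a difference of 0.0459, or of 0.0209 when the chance part was taken from the spread of the 3 controls (0.053). The fold changes had the same sign for 58.2% of genes, against 66.7% simulated (65.5% to 68.1%). Both correlations and this share lay below the simulated ranges, while the covariance lay above. In the simulation, shared controls alone thus gave correlations at least as high as those observed. The counts for independent lists leave the shared controls out of account. The 3 controls could not be split with 2 or more on each side, so part or all of the overlap may come from the shared control libraries.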

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

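Limma-voom with sample quality weights and the replicate block were chosen after the data were seen; the other settings were planned. RLE factors, no filter on low counts and leaving out the 20 most abundant and the mitochondrially encoded genes kept each of the 4 gene counts within 1.5 times. At the depths and 3 libraries per group of these data, with equal spread in every library, 20% of simulated 1.5-fold changes were called for Ind_Z against control. Depth alone was not varied. In the data the spread was unequal, with control13 at the lowest voom weight (0.144), so the simulated shares may not hold there. Except where the setting itself removed libraries or genes or raised the bar, the cause was not tested.

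For Ind_B against control (9 calls), upper-quartile factors gave 19, DESeq2 301 and voom 214, each holding all 9. The 6-library fit gave 1, which was none of the 9, and the test against 1.5-fold 0 (220 at an unadjusted p under 0.05 in edgeR). Leaving out single libraries gave 0 to 332. For Ind_Z against control (131), DESeq2 gave 446 and voom 2131, both holding all 131, the 6-library fit 59 and the 1.5-fold test 11; leaving out single libraries gave 16 to 1213. For Ind_Z against Ind_B (26), DESeq2 gave 631, voom 1501 and the 6-library fit 1251, each holding all 26, the mean count of 50 gave 14, and the 1.5-fold test 0 (274 at an unadjusted p under 0.05 in edgeR); leaving out single libraries gave 0 to 1453. For any difference (123), DESeq2 gave 911 and voom 2294, and leaving out single libraries 0 to 1467. Of the 69 calls of named genes over the comparisons, edgeR lost 46 without control1, 58 without Ind_Z replicate 2 and 61 without Ind_Z replicate 3. Without control12 it lost 7 and gained 35, and without control13 it gained 49.

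Camera's 19, 13 and 21 list calls became 0, 0 and 0 with an estimated correlation (2, 4 and 2 lists at an unadjusted p under 0.05) and 0, 4 and 0 with fry (12, 9 and 16). Of the 53 list calls, 0 took the opposite direction in any setting; RLE factors moved 1 list result across the threshold and leaving out control13 moved 18 (11 gained, 7 lost). Without control13 the direction of 12 of the 61 uncalled list results differed. The correlation of the antifoam responses, 0.44, was 0.542 without the filter and 0.34 to 0.624 without single libraries.

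No paired analysis was possible against control because only 1 control column carries a replicate number. Between the antifoam groups, same-numbered libraries did not deviate together (correlations of −0.0229, −0.238 and −0.442), and no library correlated best with its own number. The replicate block on those 6 libraries gave 572 calls, 480 higher, against 1251 in the 6-library fit without it.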

Other observations

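The tests of length and GC, both tests of a label from the antifoam groups and of growth stage for control13, those of control13 and of treatment for ergosterol, those of a shared axis and of the kind of antifoam for ribosomal proteins, and the counts of other splits were chosen only after their results, or closely related values, had been seen. The tests of depth, of scaling, of length and GC for ribosomal proteins, of abundant genes and of copies were set beforehand.

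Small nucleolar RNAs, a class outside the fixed lists, had a median change of −0.66 in Ind_B against control, with 42 of 45 lower, and of −0.24 in Ind_Z, and were higher in Ind_Z than in Ind_B by a median of 0.53, with 40 of 45 higher. In these comparisons 0 of the 45 passed edgeR's test, and 20, 1 and 6 had an unadjusted p under 0.05. Without control13 the medians were −0.56, −0.1 and 0.55, and 1 rose in the second comparison and 3 in the last. Their level (log2 CPM relative to the mean of each gene) varied within groups, at 0.44, −0.03 and 0.71 in control1, control12 and control13, at −0.8, 0.36 and −1 in Ind_B replicates 1, 2 and 3, and at −0.04 to 0.35 in Ind_Z. The noncoding RNA share of counts was 13% to 21.8% over the libraries, with SCR1, the RNA of the signal recognition particle, taking 6.53% to 11.6%.

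The first pattern is that control13 stood apart from the other controls, while control12 thinned to its depth still correlated with control1 at 0.994, which argues against depth. Length and GC explained 13% of the variance of its deviation over genes, a value between the bounds set for that test, so a partial contribution stays open; a second test, chosen after that one had left the matter undecided, found an SD of 0.578 left after removing the trend, against 0.23 between control1 and control12, which argues against length and GC as the whole of it. Its highest correlation with an antifoam library was 0.967, and its correlations with the Ind_Z libraries (0.965 to 0.967) exceeded those with the other controls (0.956 and 0.954), but correlations cannot settle a wrong label for a library this far from all others. Over the 16 genes called alike in both antifoam groups without control13, its median position was −0.497 (quartiles −0.637 and −0.234) on a scale from 0 at the other controls to 1 at the antifoam mean, which argues against an antifoam library under a control label and leaves a culture from outside these groups untested. The S phase list lay at percentile 100 of 10000 random lists of matched expression. So did the glycolysis, respiratory chain, ribosomal protein, amino acid, hypoxic and histone lists, so the deviation is not specific to the cell cycle. Further lists lay near either end, such as ergosterol at 99.42 and ribosome biogenesis at 0.01. Random lists lack the correlation between members of a real list, so these percentiles overstate how unusual a list is. A culture at another stage of growth or of the cell cycle may be the source, as a hypothesis.

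The second pattern is the lower level of ergosterol genes in both antifoam groups. Without control13 the median in Ind_B against control was −0.658, so that library is not the whole source there. With RLE or upper-quartile factors the Ind_B median was at most −0.828, which argues against scaling. Both tests were set for Ind_B only. In Ind_Z against control the median without control13 was −0.417 (camera adjusted p = 0.0227, and 0.752 with an estimated correlation). The list level was 0.51, 0.05 and 0.88 in the controls and −0.46 to 0.03 in all 6 antifoam libraries, with an exact one-sided permutation p = 0.0119 over 84 splits, the smallest they can give. Control12 at 0.05 lay next to Ind_Z replicate 2 at 0.03, so the gap was small. Such a separation was not particular to ergosterol, the list on which the permutation test was run. The nitrogen catabolite repression list lay at 0.117 to 0.227 in the controls and −0.257 to 0.092 in the antifoam libraries. The respiratory chain list lay at −0.007 to 0.651 and −0.254 to −0.025. A response to antifoam treatment is a candidate explanation, found and tested on the same data.

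The third pattern is the higher level of ribosomal protein genes in Ind_Z than in Ind_B. The median was 1.05 after removing a length and GC trend, and 0.998 without the most abundant and the mitochondrially encoded genes. These values argue against length and GC and against abundant genes as the source. Over the 121 members without a near-identical copy the median was 0.975, so the 14 members marked as having one are not the whole source. The mark does not cover copies below its limits of identity and length. Reads shared between such copies were not tested and stay open as a source. Across genes, which are not independent replicates, the difference between Ind_Z and Ind_B correlated at r = 0.67 with that between control13 and the other controls, so the same axis may separate untreated cultures, such as ones differing in growth. The list level was 0.4 to 0.54 in Ind_Z and −0.64 to −0.33 in Ind_B, while control13, without antifoam, reached 0.67 and the other controls lay at −0.3 and −0.33. The test set for the kind of antifoam needed an exact two-sided permutation p under 0.05, which 3 libraries against 3 never give (0.1 at the smallest), so it decided nothing and that explanation stays open.

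Other splits of the libraries were counted for each number of calls. For the comparisons of 2 groups, the 10 splits of 6 libraries are too few for a share under 0.05; the real splits called 9, 131 and 26 genes, 1 of the 10 splits calling as many in each, and the highest of the others called 0 in edgeR (at 1170, 1183 and 1564 genes with an unadjusted p under 0.05 in the real splits). For any difference among the groups, 100 of the 280 possible splits were drawn, the real one included. Of them 1, the real one with 123 genes, called as many, and the highest of the others called 8. A share of 1 in 100 argues against a random grouping of all 9 libraries. It does not exclude one, since the test was chosen after the counts had been seen. The count for any difference was 0 in edgeR without Ind_Z replicate 2 or 3 (1040 and 1035 at an unadjusted p under 0.05). It was 12 without control1 and 1467 without control13, and DESeq2 on all libraries called 911.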
